A study of Mus musculus with 4 samples.

How the data were processed

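The series holds 4 libraries from CD45-positive cells of peritoneal lavage fluid. A gene expression library and a B-cell receptor (BCR) library, both made with 10x Genomics droplets, came from wild-type (WT) mice, and the same pair came from knockout (KO) mice. The gene that was knocked out is not reported here. Per the labels, all mice were fed a high-fat diet for 3 months from 4 weeks of age. The number of mice behind each library is not given in the sources used here.

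The deposited expression files hold unnormalised counts of unique molecular identifiers (UMIs) per gene and barcode for 32285 genes, and no barcode had fewer than 500 UMIs. Per the file headers, the matrices were written by Cell Ranger 6.1.2, whereas the submitters' processing notes name Cell Ranger 6.0.1, Seurat 4.3.0 and the build mm39. The header and the notes differ, so the version and annotation behind the counts are uncertain, and no genome coordinates are given. The labels name a 3' gene expression kit, but immunoglobulin V segments were abundant in the expression libraries, so the end of the transcript that was read is uncertain. The deposited BCR files hold read and UMI counts per assembled contig with V, J and constant gene and CDR3 sequence. Every contig in them was marked as high-confidence, full-length and productive. The gene names are those of the files.

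Barcodes with at least 200 genes and under 10% mitochondrial UMIs were kept. Doublet scores were computed per library with Scrublet as implemented in scanpy 1.11.5. Its automatic threshold marked 2 barcodes in the WT library, so the caller had not worked there. The highest-scoring barcodes were removed instead, up to a rate of 0.8% for every 1000 scored barcodes (8.06% in WT and 18.0% in KO). Barcodes tied at the threshold score, 129 in WT and 241 in KO, were kept, so that 6.98% and 17.5% of the scored barcodes were removed. This rule was chosen after the automatic threshold had been seen, and the automatic threshold was run as an alternative. Among barcodes that passed the other filters it removed 703 in WT and 3931 in KO and left 9315 and 18396. Kept barcodes had a median of 6076 UMIs in WT and 2958 in KO.

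Both libraries were clustered together, without batch integration. Counts were normalised to 10000 per barcode and log-transformed, 2000 variable genes were chosen with scanpy, and 30 principal components were taken. Leiden clustering (leidenalg 0.10.2, resolution 1) was run on a graph of shared neighbours among the 15 nearest. Immunoglobulin, T-cell receptor segment, mitochondrial, ribosomal, haemoglobin, Xist and Y-linked genes were left out of the variable genes. Clusters were named from marker genes fixed before the data were examined, and the classes are therefore B-1-like, B-2-like, T-like and so on, written below without the suffix. The scoring rule that turns markers into names was set after the data were seen. A cluster stayed unnamed where no class scored above 1 log2 unit, where a second class above that score came within 0.5 log2 units of the best, where a class without CD3 carried T-cell markers, where UMIs were low and no marker led, or where another class had more markers among the 10 leading genes. B-cell clusters with B-1 and B-2 scores within 0.5 got no subset name. Unnamed clusters held 6.30% of WT and 5.36% of KO barcodes, and B-cell clusters with no subset name held 1.35% and 2.01%.

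For each class, UMIs were summed per library and expressed as CPM, the UMIs of a gene scaled to the UMI total of the class. KO to WT ratios carry exact conditional binomial 95% intervals, single CPM values exact Poisson intervals, and shares of barcodes exact Clopper-Pearson intervals. Intervals of a ratio of shares use the normal approximation on the log scale. All of these cover counting error only. With 1 library per genotype there is no estimate of the spread between mice, so no test between genotypes was made and no p-value is given. Where a share is 0, the limit given is that of 3 counts. The designs, gene lists, markers and rule for named genes were fixed before the data were examined. The rule took genes at 50 CPM or more in at least 1 library whose ratio interval lay wholly above 1.5 or below its inverse. The 12 highest and 12 lowest ratios were taken in each of the 3 largest classes, and the 5 highest and 5 lowest in other classes with at least 200 barcodes in both libraries. Immunoglobulin, T-cell receptor, sex-linked, mitochondrial, ribosomal and haemoglobin genes and predicted genes were left out of the ranking. To these were added up to 4 members of each gene list at 50 CPM or more with the largest absolute log2 ratio, the class markers, Xist and Y-linked genes.

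For each of 30 gene lists, the median log2 ratio of members at 10 CPM or more was taken relative to the median of all genes at that level. Members are called higher or lower relative to that median, and immunoglobulin genes do not enter it. The list median was set against 10000 random lists of the same size matched on mean expression. The resulting percentile describes these libraries only. Lists with fewer than 5 members at that level were not summarised. The intervals drawn beside list medians come from 1000 Poisson redraws of the summed counts.

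In the BCR libraries the productive heavy chain with most UMIs was taken per barcode (6041 in WT and 13190 in KO). Barcodes were joined to the expression library of the same genotype for their class. V genes were named by the 5 highest and 5 lowest ratios among those at 0.5% or more in at least 1 library, besides Ighv11-2, Ighv12-3 and Ighv1-55. A clone was defined by identical heavy-chain V gene, J gene and CDR3 nucleotides. Measures of clone size were computed after thinning KO to the WT number of barcodes, as the mean of 100 draws. All shares and clone sizes are per barcode, since heavy-chain pairs recurred among KO barcodes.

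The ratio, interval, named-gene and list steps were tested on simulated Poisson counts drawn from the real class means. In the B-1 simulation over 2387 genes, 100% of 100 genes changed 2-fold and 100% of 100 genes changed 4-fold met the rule. In the NK simulation over 3094 genes, 62% of the 2-fold and 100% of the 4-fold changes did. No unchanged gene among those simulated in these 2 classes met it. The simulated counts follow the same counting model as the intervals, so they cannot show false calls from variation between barcodes or mice. In the real data Jchain in T cells met the rule with 99.8% of its WT UMIs in 1 barcode. Alternatives covered the gene and mitochondrial filters, doublet removal, clustering resolution, separate clustering of each library, thinning to 1000 UMIs, scaling with TMM factors (edgeR 4.0.16) or median-of-ratios factors, and the definition of clones. Further alternatives were added after seeing the data. Gene IDs were looked up in GENCODE vM21, in which 99.6% were found, and the comparison of genes across 4 classes was made over those. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and R 4.3.3 were used.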

Results

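Immune cells of the peritoneal cavity were compared between wild-type and knockout mice on a high-fat diet, to describe their composition, expression and B-cell receptors. Each genotype was represented by 1 expression library and 1 BCR library. The WT expression library held 10087 barcodes and 81817635 UMIs, with a median of 6362 UMIs per barcode. The KO library held 22516 barcodes and 103953298 UMIs, with a median of 3298. The 2 libraries therefore differed in depth per barcode as well as in genotype, and there was no replicate of either.

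Both libraries had the profile of male mice. Xist, the X-inactivation transcript, was at 3 UMIs in WT and 2 in KO, and the Y-linked gene Ddx3y was at 57.8 and 57.3 CPM.

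The question of composition was addressed by the share of kept barcodes in each class. B cells made up most of both libraries, at 69.2% (68.2 to 70.1) of WT and 71.3% (70.7 to 72.0) of KO barcodes. B-1 cells, the self-renewing B cells of body cavities that make natural IgM, had a lower share in KO (40.1%) than in WT (45.1%), a ratio of 0.888 (0.863 to 0.914). B-2 cells, the conventional follicular type, had a higher share in KO (29.2% against 22.7%), a ratio of 1.29 (1.23 to 1.35). Of the B-2 clusters only cluster 5 was higher in KO, at 2.30% of WT and 13.2% of KO barcodes. Clusters 1 and 8 were at ratios of 0.745 and 0.949. Cluster 5 was also the shallowest of them, with median UMIs of 1944 in WT and 1473 in KO, against 3900 and 3006 in cluster 1. Whether depth per barcode set the division between these clusters was not tested. In cluster 5, 75.4% of KO and 20.6% of WT barcodes with 1 heavy chain were in clones of at least 2 barcodes. T cells were 1617 of the 9315 WT and 2766 of the 18396 KO barcodes, a ratio of 0.866 (0.819 to 0.916). NK cells were at 3.65% and 3.23%, a ratio of 0.885 (0.776 to 1.01), an interval that holds 1. The B-1 ratio turned to 1.38 when each library was clustered on its own, a setting in which B cells with no subset name held 18.9% of WT and 1.78% of KO barcodes. When no doublets were removed, the ratio of all B cells turned to 0.980. That of NK cells, whose interval had held 1, moved to 1.07.

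Myeloid classes were small and had higher shares in the KO library. Small peritoneal macrophages, which derive from monocytes, were at 0.966% (90 barcodes) in WT and 1.58% (290 barcodes) in KO, a ratio of 1.63 (1.29 to 2.06). With each library clustered on its own, that ratio was 1.23 (0.976 to 1.55), an interval that holds 1. Large peritoneal macrophages, the resident GATA6-dependent type, were at 0.376% (35 barcodes) and 0.707% (130 barcodes), a ratio of 1.88 (1.30 to 2.73). Conventional dendritic cells were at 1.80% and 2.22%, a ratio of 1.23, and dividing cells at 0.365% and 0.544%. The ratio of dendritic cells turned to 0.909 with a mitochondrial limit of 20% and to 0.911 at the lower clustering resolution. Shares are shares of sorted CD45-positive barcodes, and heavy-chain pairs recurred among KO barcodes, with values given under the BCR libraries.

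**Figure D1:**
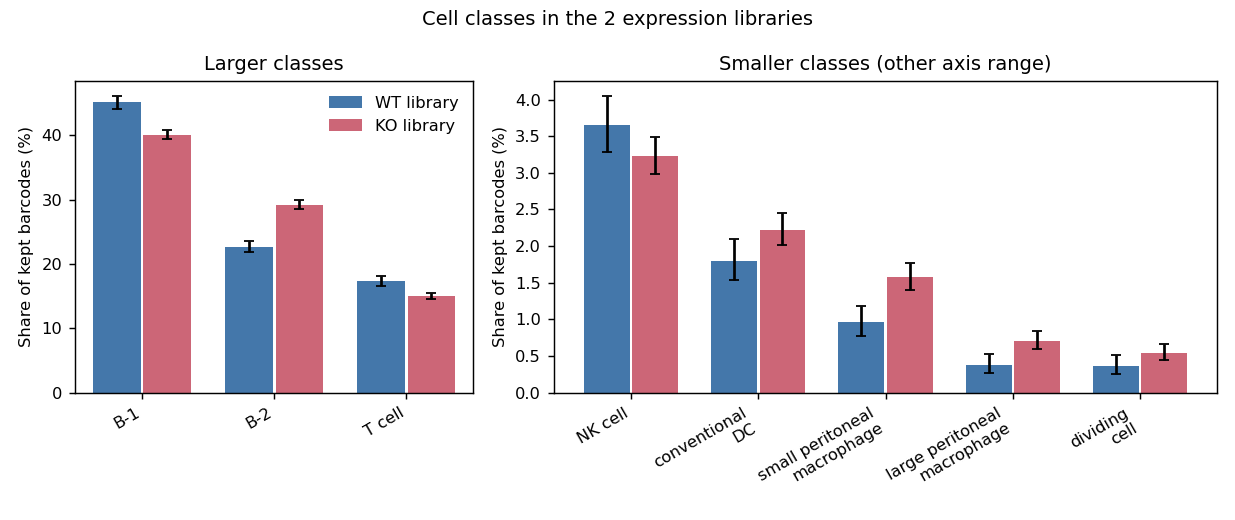
Share of kept barcodes per cell class in the WT and KO expression libraries, in percent, with bars for each library and exact 95% binomial intervals that cover counting error only. B-1 cells take 45.1% in WT and 40.1% in KO, B-2 cells 22.7% and 29.2%, and the small classes are drawn on their own axis range.

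In B-1 cells, the transcriptional co-repressor gene Irf2bp2 had the lowest ratio of the ranked genes, at 392 CPM in WT and 137 CPM in KO, a ratio of 0.351 (0.340 to 0.362). Sfr1, whose product takes part in homologous recombination, was at 0.510 (0.489 to 0.531), and the adhesion molecule gene Epcam at 0.586 (0.553 to 0.620). Higher in KO were Zyx, which encodes the focal adhesion protein zyxin, at 1.93 (1.79 to 2.08), and Mgst2, a microsomal glutathione transferase gene, at 1.88 (1.75 to 2.02). Trim34a, Trim12a and Trim11, of the tripartite motif family, were at 1.73, 1.69 and 1.69, and the transcription factor gene Zeb2 was at 1.62 (1.54 to 1.70). Fchsd2 was at 1.59. Trim34a and Trim12a belong to a family of close paralogs, so the division of their counts is uncertain.

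The B-1 identity list was lower in KO B-1 cells, with 13 of 19 measured members lower and a median log2 ratio of -0.15, at the 0.005 percentile of matched random lists. Most members of this list and of the B-2 and follicular list are also markers that named the clusters. Their medians therefore depend on how barcodes were divided among the clusters. Nfatc1, a calcium-dependent transcription factor gene, was at 0.853 (0.827 to 0.880), Bhlhe41, a transcription factor gene of B-1a cells, at 0.858 (0.813 to 0.905), and Cd9 at 0.865. Plscr1 went the other way, at 1.16. The largest cluster of WT B-1 barcodes was cluster 4 (1629), and most KO B-1 barcodes were in clusters 2 and 3 (2452 and 2485). Cluster 4 was also the deepest B-1 cluster, with median UMIs of 10736 in WT and 8181.5 in KO, against 8271 and 4176 in cluster 3. The part of depth in this mix was not tested. With clusters weighted alike, the list median was -0.06. The B-2 and follicular list was higher in KO B-1 cells (11 of 14 members, median 0.09), with Foxo1, a transcription factor gene, at 1.27 (1.21 to 1.32), and its median was 0.01 with clusters weighted alike. Ighd, an immunoglobulin gene outside the median, was at 1.41 (1.32 to 1.51).

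Growth and protein-folding genes were lower in KO B-1 cells. Of 25 measured MYC and mTORC1 targets, 23 were lower, with a median of -0.15 that lay below all random lists. Odc1, which encodes the first enzyme of polyamine synthesis, was at 0.676 (0.660 to 0.692), and Phgdh, of serine synthesis, was at 178 CPM in WT and 142 CPM in KO. In the unfolded protein response list 16 of 19 members were lower (median -0.14, percentile 0.03), among them the chaperone gene Hspa5 at 0.725 and Herpud1 at 0.816. Ribosomal protein genes were lower in 36 of 40 cases (median -0.10, percentile 0.355), with Rpl38 at 0.745. Nuclear-encoded oxidative phosphorylation genes were lower in 34 of 41 cases (median -0.09), with Ndufa1 at 0.780 and Atp5e at 0.806. Gapdh, of glycolysis, was at 0.695 (0.682 to 0.708). Mitochondrially encoded transcripts went the other way (10 of 13 higher, median 0.17, percentile 99.99), with mt-Atp6 at 1.31 and mt-Co3 at 1.20.

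The B-cell receptor signalling list had a median of 0.02 in B-1 cells (14 members higher and 12 lower, and -0.03 with 1 barcode per clone), with the receptor genes Cd22 at 1.32 (1.26 to 1.38) and Fcgr2b at 1.30 (1.26 to 1.35). Genes of MHC class II were slightly higher in 12 of 13 cases (median 0.06, percentile 95.6, and 0.04 with clusters weighted alike), with H2-Aa at 1.15. The T-cell effector list had a median of 0.14 in this class (5 of 7 members higher), which turned to -0.09 with clusters weighted alike. The interferon and PI3K-AKT-FOXO lists had medians of 0.02 and 0.01 in B-1 cells and lay within the middle of the random lists. In T cells the interferon list was lower in 16 of 25 cases (median -0.11, percentile 0.945). The PI3K-AKT-FOXO list was lower there in 20 of 35 cases (median -0.08, percentile 1.65).

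In B-2 cells, Irf2bp2 was again lowest, at 204 CPM in WT and 78.5 CPM in KO, a ratio of 0.384 (0.356 to 0.413). Anxa6, a calcium-dependent membrane-binding protein gene, was at 0.545 (0.506 to 0.587), and Irf1, an interferon-responsive transcription factor gene, at 0.546 (0.495 to 0.602). Pdlim1 and Sfr1 were at 0.608 and 0.616. The inhibitory receptor gene Btla was higher in KO, at 1.80 (1.57 to 2.07), as was Trim12a, at 1.71 (1.52 to 1.92).

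The unfolded protein response list was lower in KO B-2 cells too, with 15 of 19 members lower and a median of -0.15 that lay below all random lists. Hspa5 was at 0.785 (0.754 to 0.818), Xbp1, the transcription factor gene of secretory cells, at 0.792 (0.713 to 0.879) and Herpud1 at 0.828. After thinning the list median was -0.10. The list of activated and antibody-secreting cells was lower in 8 of 11 cases (median -0.12, percentile 0.74), but its median was 0.07 after thinning. The B-cell receptor signalling list was lower in 19 of 26 cases (median -0.05, percentile 1.36, between -0.03 after thinning and -0.09 with 1 barcode per clone), with Inpp5d, which encodes the lipid phosphatase SHIP1, at 0.826 (0.775 to 0.880). Cholesterol synthesis genes were lower in 9 of 11 cases (median -0.17, percentile 0.42), with the regulator gene Srebf2 at 0.864, but the median was -0.03 after thinning, -0.04 without doublet removal and -0.09 with clusters weighted alike. Mitochondrially encoded transcripts were higher (median 0.24), with mt-Atp6 at 1.33 (1.30 to 1.36). Markers of the class such as Fcer2a (0.893), Cd55 (0.878) and Cr2 (1.01, and 0.835 after thinning) differed little. Most WT B-2 barcodes were in cluster 1 (1517), and most KO B-2 barcodes in clusters 5 and 1 (2426 and 2232), with 214 WT barcodes in cluster 5.

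In T cells, most genes of the effector and exhaustion list were higher in the KO library and most of the naive and memory list lower. Of 28 measured members of the effector and exhaustion list, 25 were higher, with a median of 0.29 above all random lists. Pdcd1, which encodes the inhibitory receptor PD-1, was at 1.75 (1.52 to 2.03), the granzyme gene Gzmk at 1.66 (1.44 to 1.91) and the chemokine receptor gene Cxcr6 at 1.64 (1.52 to 1.76). The cytokine gene Il17a went the other way, at 0.639 (0.549 to 0.742). Its UMIs came from 44 WT and 68 KO barcodes, with 21.0% of WT and 9.89% of KO UMIs in 1 barcode. Without the barcode with most UMIs in each library, its ratio was 0.729. In the naive and memory list 11 of 12 members were lower, with a median of -0.27 below all random lists, among them Cd27 at 0.717, the chemokine receptor gene Ccr7 at 0.773 and Lef1 at 0.805.

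Part of this followed the mix of T-cell clusters. Cluster 12, led by Ecm1 and Ly6c1 and with Lef1 among its leading genes, held 329 WT and 313 KO barcodes, and cluster 16, led by Cd163l1, Il17a and Cxcr6, held 107 and 280. With clusters weighted alike the effector median was 0.14 and the naive median -0.13. Pdcd1 was then at 1.48, Gzmk at 1.53, Cxcr6 at 1.28, Il17a at 0.437 and Cd27 at 0.746, while Lef1 moved to 0.972. Among the ranked genes, Cd163l1, a scavenger receptor gene of gamma-delta T cells, was at 2.74 (1.88 with clusters weighted alike). Avpi1 was at 2.78, the fibrinogen-like gene Fgl2 at 2.16 and the protease inhibitor gene Serpina3g at 2.05. Irf2bp2 was at 186 CPM in WT and 66.7 CPM in KO, Prelid2 at a ratio of 0.511, Tuba1c at 0.575 and Sidt1 at 0.601. Pdlim4 (0.447), Myo6 (0.475) and Dapl1 (0.573) are leading genes of cluster 12, and with clusters weighted alike they were at 0.757, 0.669 and 0.693.

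Immediate-early and heat shock genes were lower in KO T cells (21 of 24, median -0.28, below all random lists). The early activation genes Nr4a1, Nr4a3 and Jun were at 0.475 (0.441 to 0.512), 0.550 and 0.553 (0.521 to 0.586), and the chaperone gene Hsph1 was at 0.674. The list was also lower in B-1 cells (median -0.15) and NK cells (median -0.25), but not in B-2 cells (median 0.01). With clusters weighted alike the B-1 median was -0.09, and without doublet removal the T median was -0.17. This list was fixed as one of handling stress, and the difference between classes was not tested. Ribosomal protein genes were lower in 37 of 40 cases in T cells (median -0.14, and -0.05 with clusters weighted alike), with Rps28 at 0.742, and mitochondrially encoded transcripts higher in 9 of 13 (median 0.14).

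Transcripts of other lineages were higher in KO T cells. The macrophage lysozyme gene Lyz2 was at 8.96 CPM in WT and 52.5 CPM in KO, a ratio of 5.86 (4.50 to 7.71). The B-cell receptor gene Cd79a was at 78.5 and 154 CPM, Cd79b at a ratio of 2.05, the B-cell marker gene Ly6d at 2.24, Ifi30 at 2.17 and the MHC class II genes H2-Aa and H2-Ab1 at 2.27 and 2.20. In the MHC class II list 8 of 9 members were higher (median 0.97, and 0.54 at Scrublet's automatic threshold). Leaving out barcodes with 3 or more B-cell marker UMIs gave a list median of 1.90 and ratios of 4.96 for Cd79a, 3.23 for Cd79b, 4.63 for Ly6d, 3.31 for Ifi30, 4.33 for H2-Aa and 4.43 for H2-Ab1, and without doublet removal Cd79a was at 3.19, Cd79b at 3.09 and Ly6d at 3.52. The B-2 and follicular list had a median of -0.12 in T cells (8 of 11 members lower), which turned to 0.00095 with clusters weighted alike. Jchain was at 1072 UMIs in WT and 1 UMI in KO, a ratio of 0.000984 (2.49e-05 to 0.00549). Of the 1072 WT UMIs, 99.8% came from 1 barcode, and without the barcode with most UMIs in each library the ratio was 1.58. It was 0.951 without doublet removal.

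In NK cells, the cell cycle inhibitor gene Cdkn1a had the lowest ratio, at 122 CPM in WT and 41.0 CPM in KO, a ratio of 0.335 (0.240 to 0.462). Pdlim1 was at 0.439 (0.688 without doublet removal), Sfr1 at 0.526 and Nr4a1 at 0.578 (0.516 to 0.647). The T-cell effector list, which holds cytotoxic genes, had 13 members higher and 14 lower (median -0.09, percentile 10.6, and 0.01 after thinning). Ncr1, which encodes the activating receptor NKp46, was at 0.650 (0.598 to 0.706), the perforin gene Prf1 at 0.788 (0.708 to 0.877), Eomes at 0.745 (0.659 to 0.843) and Ifng at 0.631 (0.529 to 0.751). Irf7, a regulator of interferon responses, was at 0.576 (0.462 to 0.715), while the interferon list had 10 members higher and 11 lower (median -0.03). Nuclear-encoded oxidative phosphorylation genes were lower in 32 of 41 cases (median -0.17, percentile 0.065), with the cytochrome c gene Cycs at 0.683. Mitochondrially encoded transcripts were higher in 11 of 13 (median 0.21, and 0.41 without doublet removal). Myc was higher, at 2.21 (1.78 to 2.76), and was at 1.30 without doublet removal. The lipid uptake and lipid-associated lists had medians of -0.29 and -0.28, with Lgals3 at 0.558, but after thinning their medians were 0.055 and 0.00046.

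B-cell transcripts were also higher in KO NK cells. Ly6d was at 12.2 CPM in WT and 142 CPM in KO (ratio 11.6, 6.88 to 21.2), and Cd79a, Cd79b and H2-Ab1 were at 7.97, 7.53 and 8.13. Lyz2 was at 7.60 (3.92 to 16.4). All 10 measured MHC class II genes were higher, with a median of 1.98 (0.66 without doublet removal). The MHC class I list had a median of 0.09 (12 of 15 members higher), which turned to -0.03 without doublet removal. Without doublet removal, Ly6d, Cd79a, Cd79b and H2-Ab1 were at 1.39, 1.60, 1.42 and 1.55, and at Scrublet's automatic threshold at 4.75, 3.87, 4.02 and 3.68. Leaving out barcodes with 3 or more B-cell marker UMIs gave 4.82 for Ly6d, 4.18 for Cd79a and 3.46 for Cd79b. The class held 340 WT and 594 KO barcodes, with 1227773 and 1293118 UMIs, the fewest of the 4 classes described, which limits its precision.

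**Figure D2:**
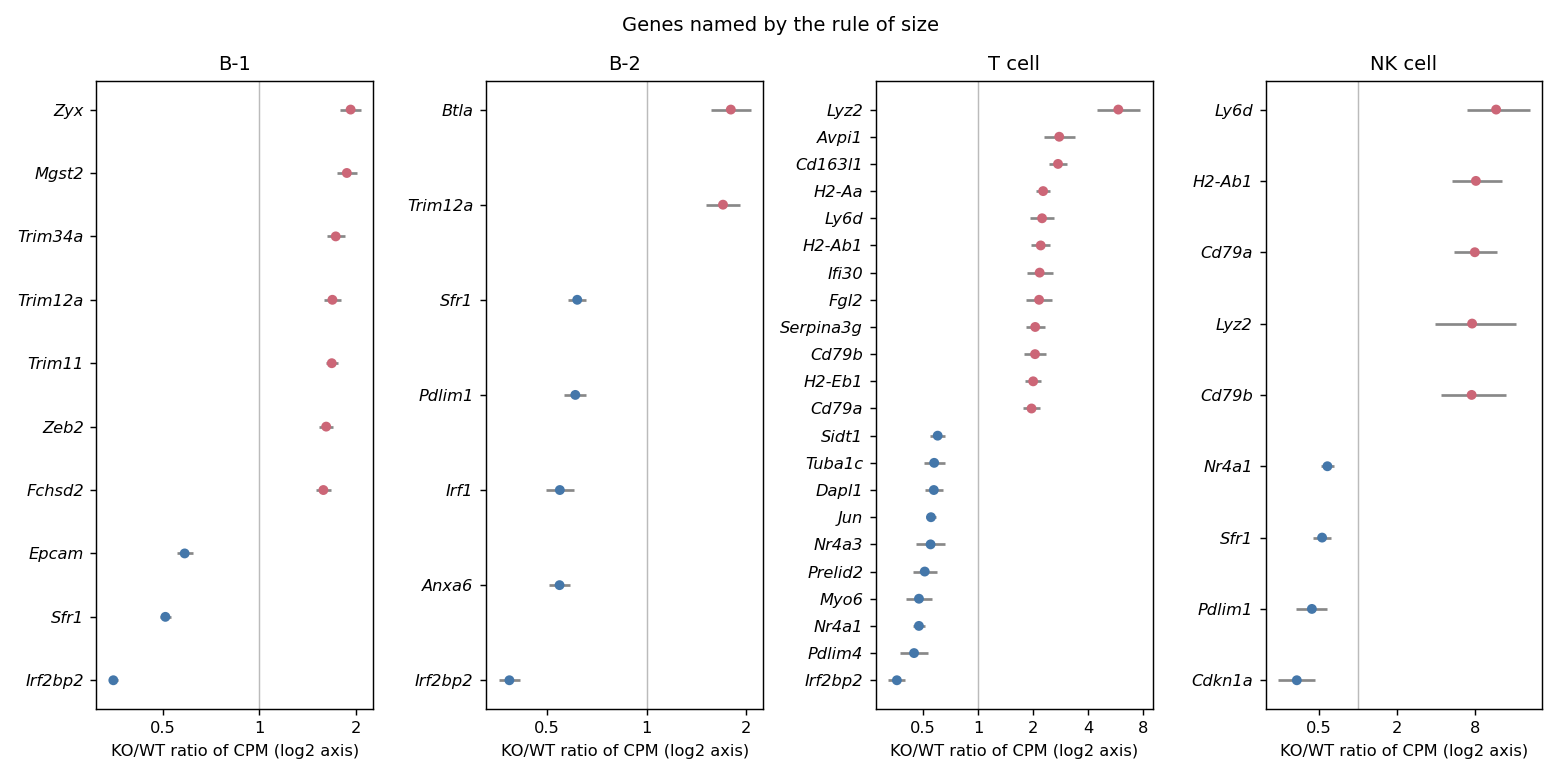
KO to WT ratio of CPM for the genes ranked by the size rule in each of 4 cell classes, on a log2 axis, with points for the ratio and lines for the exact 95% interval of counting error, and without Jchain in T cells, which rests on 1 WT barcode. Irf2bp2 lies at 0.351 in B-1 and 0.384 in B-2 cells, and the B-cell genes Ly6d, Cd79a and Cd79b lie above 7 in NK cells.

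**Figure D3:**
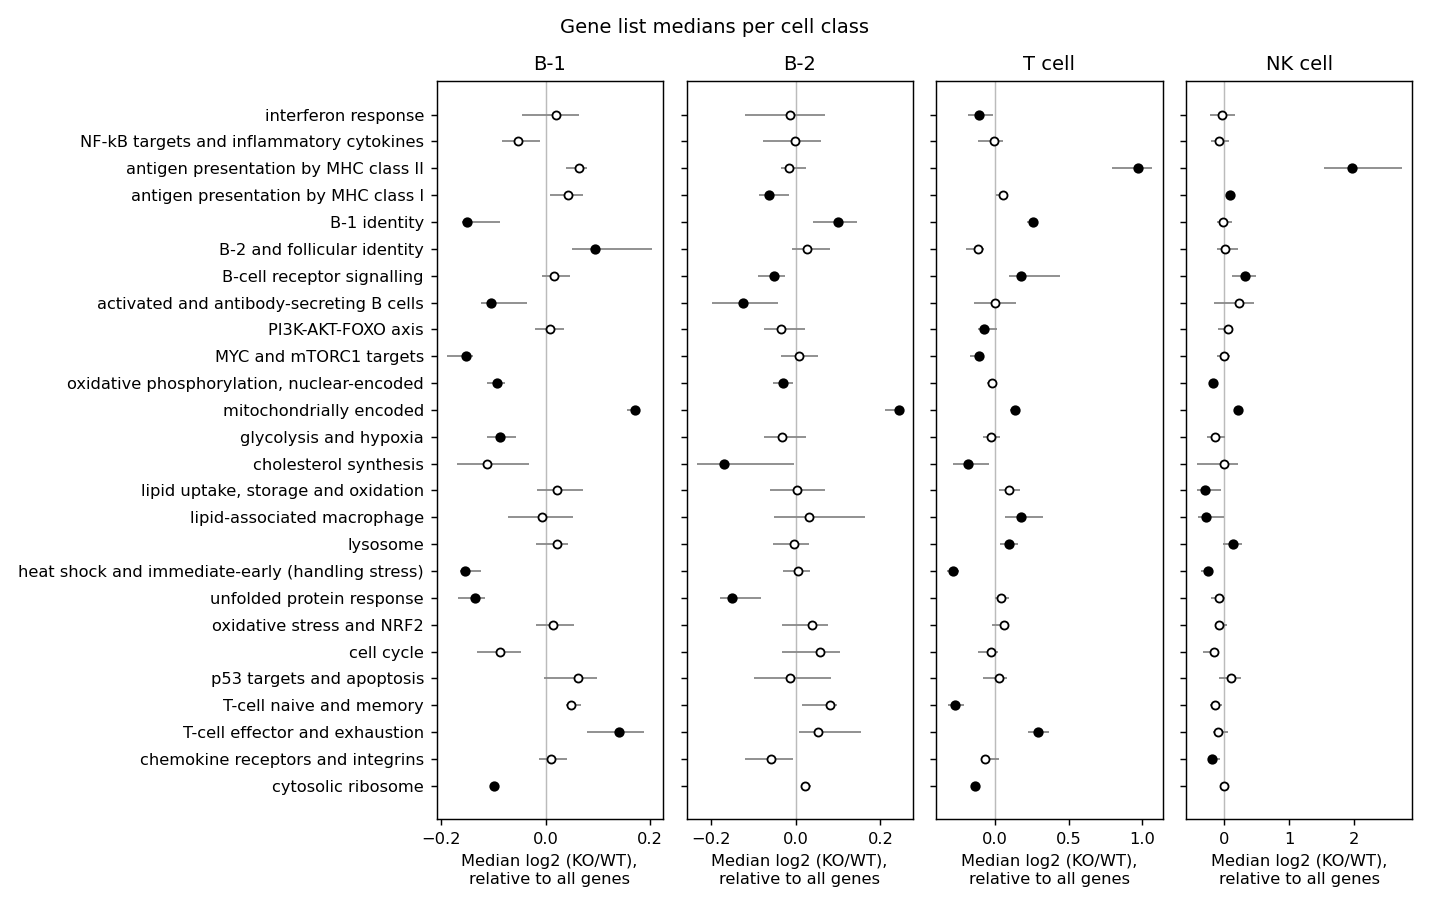
Median log2 KO to WT ratio of each gene list relative to all genes in each of 4 cell classes, with a separate axis range per class and lines for 95% intervals from Poisson redraws, points being filled where they lie outside the middle 95% of 10000 matched random lists. Mitochondrially encoded genes lie above 0 in each class (0.17, 0.24, 0.14 and 0.21), and the class II antigen presentation list reaches 1.98 in NK cells.

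The BCR libraries addressed how the antibody repertoire compared. The V genes Ighv11-2 and Ighv12-3, which B-1a cells use for antibodies to phosphatidylcholine, took a smaller share of heavy-chain barcodes in KO. Ighv11-2 was at 8.33% (7.64 to 9.05) in WT and 4.24% (3.90 to 4.60) in KO, a ratio of 0.509 (0.453 to 0.572). Ighv12-3 was at 10.1% (9.35 to 10.9) and 6.22% (5.81 to 6.64), a ratio of 0.616 (0.557 to 0.681). Of their usual light-chain partners, Igkv14-126 was at 8.10% and 4.03% and Igkv4-91 at 5.97% and 4.05%. Within B-1 barcodes the ratio was 0.611 (0.538 to 0.695) for Igkv14-126 and 0.884 (0.764 to 1.02) for Igkv4-91, an interval that holds 1. Ighv1-55 was at 3.08% and 2.47%.

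Within B-1 barcodes the summed share of Ighv11-2 and Ighv12-3 was 27.2% (25.6 to 28.7) in WT and 18.7% (17.7 to 19.7) in KO, a ratio of 0.688 (0.636 to 0.745). Among the V segments counted in the expression libraries, Ighv11-2 was the most abundant in 19.4% of WT and 12.8% of KO B-1 barcodes with any, a ratio of 0.661 (0.606 to 0.720), and took 25.7% and 17.0% of V segment UMIs. Ighv12-3 was the most abundant in 671 of 4194 and 1007 of 7303, a ratio of 0.862 (0.788 to 0.943), but took similar shares of V segment UMIs, at 19.3% in WT and a ratio of 0.983. T barcodes, which should lack these transcripts, gave 18.9% in WT and 9.79% in KO for Ighv11-2 and 14.2% and 11.3% for Ighv12-3 among those with any V segment, at median depths of 4351 and 2177 UMIs against 8673 and 4268 in B-1 barcodes. B-2 barcodes went the other way, at 0.723% and 1.19% for Ighv11-2 and 0.579% and 0.917% for Ighv12-3, with ratio intervals that hold 1. Of the other V genes at 0.5% or more of barcodes in at least 1 library, Ighv5-4 had the highest ratio, at 2.21 (1.60 to 3.05), followed by Ighv1-5 (1.83), Ighv1-54 (1.55), Ighv9-1 (1.48) and Ighv2-2 (1.43). Under the same limit Ighv9-4 was lowest, at 0.692 (0.483 to 0.991), followed by Ighv6-6 (0.732), Ighv2-6 (0.763), Ighv5-16 (0.773) and Ighv4-1 (0.804). The ratio intervals of Ighv9-1, Ighv2-6, Ighv5-16 and Ighv4-1 hold 1.

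IgM was the constant region of 96.4% of WT and 94.9% of KO heavy-chain barcodes. IgD was higher in KO, at 3.75% (495 of 13190) against 2.37% (143 of 6041), a ratio of 1.59 (1.32 to 1.90). Within B-2 barcodes it was 6.29% (5.23 to 7.48) in WT and 7.73% (6.97 to 8.55) in KO. Class-switched chains were at 1.13% and 1.17%, a difference not detectable at this depth. No IgE barcode was found, which allows a share of up to 0.0497% in WT and 0.0227% in KO.

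The 3 largest clones were the same in both libraries. Ighv11-2 with the CDR3 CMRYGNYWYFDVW held 183 WT and 199 KO barcodes, and Ighv11-2 with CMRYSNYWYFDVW held 171 and 137. Ighv12-3 with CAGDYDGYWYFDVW held 62 and 124. After thinning, the 10 largest clones held 9.42% of WT and 5.23% of KO barcodes, and Simpson's index times 1000 was 2.04 and 0.558. Clones of at least 2 barcodes went the other way, at 30.6% in WT and 39.7% in KO. The difference was widest in B-2 barcodes, at 3.25% in WT and 22.9% in KO.

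Beside these clone sizes stands a measured difference between the libraries. Of KO barcodes with 2 different heavy chains, 52.9% (50.5 to 55.3) shared the same pair with another barcode (891 of 1684), against 8.42% of WT (47 of 558). After shuffling the second chain among these barcodes, the highest of 1000 counts was 6 in KO and 2 in WT. Without thinning, 34.3% to 86.3% of KO and 2.22% to 65.3% of WT heavy-chain barcodes of the B-1 and B-2 clusters were in repeated clones, with the KO value higher in each cluster. Shares and clone sizes are therefore given per barcode.

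**Figure D4:**
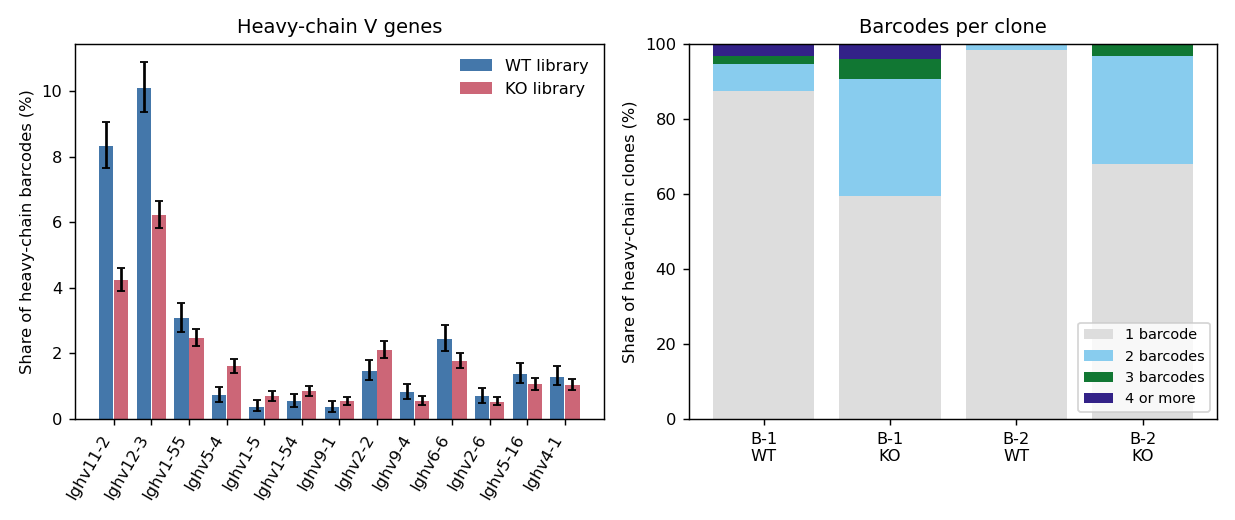
Left, share of heavy-chain barcodes per V gene in percent in the WT and KO BCR libraries, with exact 95% binomial intervals, and right, share of heavy-chain clones by the number of barcodes they hold, in percent, for B-1 and B-2 barcodes of each library. Ighv11-2 is at 8.33% in WT and 4.24% in KO, and clones of 2 barcodes number 27 in WT and 855 in KO B-2 barcodes.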

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

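The tests of repeated pairs, of mitochondrial percentages and of Ighv11-2 and Ighv12-3 were chosen after the results had been seen, and they compare the libraries, not the genotypes.

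The recurrence of heavy-chain pairs, in data that the comparisons of composition and expression do not use, stood out at 52.9% of the KO barcodes with 2 heavy chains. Among B-2 barcodes, 855 KO and 27 WT clones held 2 barcodes. A candidate explanation is that 1 droplet, with its doublet content, was counted under several barcodes. In that case the KO intervals are too narrow. The KO doublet rate of 18.0%, set from the number of barcodes, may then be too high. The KO shares may then be shifted as well, since repeated clones held 34.3% of KO barcodes in cluster 1 and 75.4% in cluster 5. Over barcodes with 1 heavy chain, B-2 per B-1 was 0.611 in WT and 0.812 in KO, and over their clones 0.884 and 1.09. The pairs of KO B-2 clones differed by a median of 0.307 percentage points of mitochondrial UMIs, within the 0.268 to 0.322 of 100 binomial draws with 1 mitochondrial percentage per pair, whereas WT B-2 pairs (0.678), WT B-1 pairs (0.522) and the lowest of 100 draws of random KO B-2 partners (0.573) lay above the highest sampling draw of their own pairs (0.411, 0.204 and 0.322). This argues against expansion as the whole cause, but some expansion stays open, and KO B-1 pairs, at 0.284, lay above their highest sampling draw of 0.260 and below their lowest draw of random partners of 0.683.

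The summed share of Ighv11-2 and Ighv12-3 was lower in the KO library. With each clone counted once the ratio was 0.479 (0.399 to 0.575). Barcode numbers were not made equal for this count (6041 in WT and 13190 in KO), so that ratio cannot decide about large clones. For Ighv12-3 a few large clones do not account for all of it, since KO held fewer clones (157 against 197) among more barcodes. For Ighv11-2 the clone numbers were close (45 in KO and 49 in WT). Its 2 largest clones held 3.03% and 2.83% of WT and 1.51% and 1.04% of KO barcodes, so large clones stay open there. A lower B-1 share does not account for the lower summed share, since the ratio within B-1 barcodes was 0.688. For Ighv11-2, lower recovery of its chains does not either, since in B-1 barcodes of the expression libraries its ratio was 0.661. Transcripts from other cells may add to this, although T barcodes (18.9% and 9.79%) and B-2 barcodes (0.723% and 1.19%) differed in opposite directions. For Ighv12-3, lower recovery cannot be told apart from fewer such cells, because it led a smaller share of B-1 barcodes (0.862) but took a similar share of V segment UMIs (0.983). The mix of B-1 clusters also differed (cluster 4 held 17.5% of WT and 6.51% of KO barcodes) and was not tested as a cause, and other differences between the libraries or the mice stay open, genotype among them.

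The B-1 identity list differed in direction between classes, at -0.15 in B-1 barcodes and 0.10 in B-2 barcodes. The B-2 value was 0.21 with clusters weighted alike, 0.23 without cluster 5 and 0.03 over members at 50 CPM or more, and the B-1 value -0.06 with clusters weighted alike. This difference between the classes was not tested, and most members of the list are also markers that named the classes. An unnamed cluster led by Tnfrsf4, Areg and Foxp3 held 0.880% of WT and 1.22% of KO barcodes. It scored highest for ILC2, a class of innate lymphoid cells without CD3 (3.02), with T cells second (2.20). Il1rl1, Klrg1 and Gata3 were also among its leading genes. Foxp3 is a gene of regulatory T cells, and the identity of the cluster stays open. A B-cell cluster led by the interferon-induced genes Ifit3, Isg15 and Ifit1 held 0.429% of WT and 0.223% of KO barcodes. Both clusters stand outside the named classes.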

How the results depend on the processing

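No paired analysis was possible because each genotype had 1 library of each kind. The automatic doublet threshold, equal cluster weights, 1 barcode per clone, isotypes with each clone once, and leaving out cluster 5, a gene's top barcode or barcodes with B-cell marker UMIs were chosen after seeing the data. A direction is said to turn where the interval as reported had excluded no change. No scaling alternative turned any of the 150 named gene ratios, and list medians, taken relative to all genes, cannot test scaling. Over all alternatives 1586 gene values kept within their interval, 287 moved and 3 turned. For the 104 list medians these numbers were 1230, 156 and 7, and among the 156 were 22 that changed sign from an interval that held 0. Without doublet removal the share ratios were 0.854 for B-1, 1.20 for B-2, 0.814 for T, 1.07 for NK, 1.58 for dendritic cells, 2.13 for small macrophages and 0.980 (reversed) for all B cells. At resolution 0.5 they were 0.863 for B-1, 1.38 for B-2 and 0.911 (reversed) for dendritic cells, and with a mitochondrial limit of 20% 0.909 (reversed) for dendritic cells, because a single small cluster kept that name. With each library clustered on its own they were 1.38 (reversed) for B-1, where B cells with no subset name rose to 18.9% of WT barcodes, 1.37 for B-2 and 1.23 for small macrophages (an interval that holds 1), and thinned to 1000 UMIs 0.829 for B-1. The B-1 identity median in B-1 cells was -0.18 without doublet removal, -0.17 at the automatic doublet threshold, -0.062 with clusters weighted alike and -0.20 with 1 barcode per clone. The T effector median in T cells was 0.14 with clusters weighted alike and 0.21 over members at 50 CPM or more. Directions turned for the effector list in B-1 cells (-0.089 with clusters weighted alike, -0.077 with 1 barcode per clone), Zcwpw1 in B-1 cells (0.897 with 1 barcode per clone), the antibody-secreting list in B-2 cells (0.067 thinned), and the B-2 list in T cells (0.00095 with clusters weighted alike). They also turned for Jchain in T cells (1.09 without barcodes of 3 or more B-cell marker UMIs, 1.58 without its top barcode), and in NK cells for MHC class I (-0.027 without doublet removal), lipid uptake (0.055 thinned) and lipid-associated genes (0.00046 thinned). Ighv12-3 was at 0.465 with each clone counted once. By deposited clonotype the KO to WT ratio was 0.487 for the 10 largest clones and 0.200 for Simpson's index. For clones of at least 2 barcodes it was 2.13 without thinning and 1.43 over barcodes kept in the expression library. Apart from clusters that kept or lost a name, the causes were not tested. NK values rest on 1227773 WT UMIs and macrophage and dendritic cell values on 35 to 168 WT barcodes, which limits their precision.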

Other observations

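The comparison of genes across 4 classes was chosen after the data had been seen. The macrophage and dendritic cell classes held few WT barcodes and were not ranked by the rule, but their markers differed within the classes. In small peritoneal macrophages the gene Retnla, which marks alternative activation, was at 698 CPM in WT and 1344 CPM in KO (ratio 1.93, 1.76 to 2.10). The complement genes C1qa, C1qb and C1qc were at 1.87, 1.79 and 1.87, and the lipid carrier gene Apoe at 1.59 (1.49 to 1.69). In large peritoneal macrophages Prg4, which encodes lubricin, was at 0.675 (0.644 to 0.707), the B-cell attracting chemokine gene Cxcl13 at 0.568 (0.503 to 0.641), C4b at 0.594, F5 at 0.633 and Selp at 0.620. The acute-phase gene Saa3 was higher there, at 1.84 (1.71 to 1.98). B-cell transcripts were lower in the same KO classes, with Cd79a at 776 CPM in WT and 358 CPM in KO in small macrophages and at 576 and 333 CPM in large ones. Heavy chains were found in 20% of WT and 13.8% of KO small macrophage barcodes and in 25.7% and 15.4% of large ones. In conventional dendritic cells Cd209a was at 1.27 and Clec10a at 1.45, while Cd79a was at 844 and 672 CPM. These values rest on 35 to 168 WT barcodes per class.

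Lyz2 was higher in KO in each of the 4 lymphocyte classes, at 6.74 in B-1, 4.99 in B-2, 5.86 in T and 7.60 in NK cells, and was present in 11.8% of KO and 3.71% of WT T barcodes. Haemoglobin went the other way, with Hbb-bs at 44 UMIs in WT and 1 UMI in KO B-1 barcodes. Of 107 heavy-chain barcode sequences found in both BCR libraries, 0 carried the same clone in both, while 189 clones were found in both libraries under different barcodes, 67 of them with Ighv11-2 or Ighv12-3.

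Among genes at 20 CPM or more in at least 1 library in each of the 4 lymphocyte classes, some differed in the same direction by more than 0.32 on the log2 scale in each class. Among the lower genes were Irf2bp2, the tubulin genes Tuba1a, Tuba1b and Tuba1c, the chaperone genes Hspa5 and Hsph1, and the ribosomal protein genes Rps21, Rps28 and Rpl38. Sfr1, Stip1, Btaf1, Pi4k2a and Sfxn3, which all lie on chromosome 19, were also lower in each class. The ribosomal protein list as a whole was not lower in B-2 cells (25 of 40 members higher, median 0.02). Nor was it lower in NK cells (22 of 40 members higher, median 0.003). Rps21 was at 0.716 in B-1, 0.737 in B-2, 0.725 in T and 0.707 in NK cells. Among the higher genes were Trim12a, Trim34a and Cnot8, a gene of the deadenylase complex. Cnot8 was at 1.28 in B-1, 1.45 in B-2, 1.49 in T and 1.44 in NK cells. Lyz2, a macrophage gene described above as a transcript of another lineage, was also among the higher genes. These examples were chosen after their values had been seen.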
